A study of Drosophila melanogaster with 2 samples.

How the data were processed

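The series holds chromatin immunoprecipitation sequencing (ChIP-seq) from 2 biological replicates of Drosophila melanogaster embryos, collected at 0 to 24 h as whole organisms. Per the labels, the flies were transgenic and carried a fusion of the protein toy (twin of eyeless, a Pax6-type transcription factor) with eGFP, and the fusion protein was precipitated with an antibody against GFP after sonication. Both replicates form a single group, toy-eGFP embryo ChIP, so there is no contrast between conditions. The labels point to a possible control experiment, which was not analysed here.

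Of the 8 deposited peak lists, 4 belong to the single replicates (a thresholded and a ranked list each) and 4 to the series. Per the labels, coordinates are on dm6 and the lists come from an irreproducible discovery rate (IDR) procedure, which ranks peaks by how well they repeat between 2 peak sets. The aligner and the peak caller are not given in the sources used here. Each peak carries the authors' signal value, and how the authors scaled this signal is likewise not given in the sources used here. In the ranked lists the deposited −log10 of the global IDR reached at most 5. The deposited thresholded lists held peaks with a global IDR of at most 0.01, read from the values. Per the descriptions deposited with the samples, the lists of each replicate were made from the alignments of that replicate alone and the series' lists from both, all with 1 further input that both replicates share. The signal values of replicates 1 and 2 were taken from their own lists. The thresholded lists have another input whose content is not given in the sources used here. The lists have no column names, and 8 further columns in each of the 2 ranked lists of the series could not be assigned to a replicate and were not used.

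Read depth cannot be read from peak lists and is unknown. The number of peaks was used in its place: replicate 1 had 925 thresholded and 81037 ranked peaks, replicate 2 had 1098 and 115142. Shares of peaks are given with Wilson 95% intervals, which cover counting error only. Tests across peaks, windows or genes treat these as units, and they are not biological replicates. A p-value from them describes these lists and not the spread between embryo collections.

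The series' conservative thresholded list was the main peak set, and the series' other thresholded list is called the pooled list. Coordinates are printed 1-based on dm6. Genes came from Ensembl release 115 (BDGP6.54, the same assembly as dm6), and sequence from the RefSeq Release 6 assembly; the end of every peak on the 7 chromosome arms 2L, 2R, 3L, 3R, 4, X and Y lay within the length of the reference arm. A peak was assigned to the protein-coding gene with the nearest transcription start site (TSS) to its summit. A summit within 500 bp of the TSS of any gene was called promoter-proximal, and the others were classed by the annotation under the summit. Background for location and arm was the ranked peaks of the same list that overlapped no thresholded peak, here called not passing, 47 of which met the IDR of 0.01 but are not in the authors' list. It was compared by 2-sided Fisher's exact test with Benjamini-Hochberg adjustment over the classes or arms.

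Overlap of replicates required any shared base, and its chance level came from 1000 placements of the replicate 1 peaks on their own arms. Signal values of the replicates were compared across peaks by Spearman correlation, and promoter signal with other signal by 100000 permutations of the difference in medians. Genes of 19 fixed lists were counted as bound where a conservative peak was assigned to them. Each count was compared with 100000 random lists of the same size drawn from the genes with at least 1 ranked peak and matched on the number of ranked peaks in up to 20 bins. Drawing such lists is a permutation of list membership within bins. The test was 2-sided, and 4 listed symbols were renamed to their current form. The lists included markers of neurons, glia, muscle, endoderm, fat body, hemocytes, epidermis and trachea, since whole embryos were used. The 13 fixed motifs and all 2080 strand-collapsed 6-mers were counted as present or absent in windows of 201 bp on the summits and in windows moved by 1000 bp toward higher coordinates. These pairs were compared by exact 2-sided McNemar tests with Benjamini-Hochberg adjustment.

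The gene lists, the motifs and the rule for named genes were written before the data were examined. Named genes were: the genes nearest to the 20 strongest conservative peaks, every retinal determination and Pax family gene with a conservative peak, and for each other list up to 4 bound genes with the strongest peaks. All fixed motifs and the 10 6-mers with the smallest p were to be named. Genes without a conservative peak, and any other gene outside this rule, were named after their values were seen.

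The routines were tested on simulated data. Simulated binding was set to rise with a gene's number of ranked peaks, over 11541 genes. Lists with no added effect were drawn with preference for genes with many ranked peaks. Of 760 such lists, 2.5% fell under a permutation p of 0.05 with matching, and 46.6% under a Fisher's exact p of 0.05 without it. The 46.6% follows from these settings and is not an error rate for the real lists. Of 40 lists of 16 genes with added binding in 50% of them, 97.5% were recovered. Among 1402 simulated windows, compared with as many of the same base composition, 0 of 13 motifs were called with nothing planted. The real summit and flank windows differed in G and C (37.1% against 42.6%), so this could not show false calls from composition. A paired domain site planted in 15% of windows was recovered, as were 6 of its 6 6-mers, with 2 others called.

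Alternatives were the series' other thresholded list, each replicate's own list, stronger peaks, other distances, windows, controls, assignments and overlap rules. A count was taken as moved beyond 1.5 times the main count, and a correlation beyond a difference of 0.1. A stricter IDR of 0.001 and correlations over ranked peaks were added after seeing the data, because a planned IDR of 0.01 turned out to be the lists' own. Peaks on scaffolds outside the arms were left out of comparisons by arm, gene or sequence. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.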

Results

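Binding of toy-eGFP was mapped by ChIP-seq with an anti-GFP antibody in 2 biological replicates of whole Drosophila melanogaster embryos aged 0 to 24 h. The protein toy (twin of eyeless) is a Pax6-type transcription factor that acts upstream of eyeless (ey) in the eye primordium. Replicate 1 had 925 peaks past the authors' IDR threshold and replicate 2 had 1098. The conservative list of the series held 1404 peaks, of which 1402 lay on chromosome arms, with a median width of 340 bp and a median signal value of 106 in the authors' units. The other thresholded list of the series, the pooled list, held 1895. The summed length of the 1404 peaks equalled 0.317% of the sequence of the arms, and the 1402 on arms were assigned to 1128 of 13968 protein-coding genes, 202 of which had 2 or more peaks.

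The 20 strongest toy-eGFP peaks lay at promoters or in introns, and no test was made of what their genes share. The peak with the highest signal value, 1490.1, was in an intron of CG11050 (FBgn0031836; 2L, 6612550 to 6612885, dm6), 1021 bp from the TSS; replicate 1 gave 775 there and replicate 2 gave 694. Next came promoter peaks of CG14100 (FBgn0036889; 3L, 19590480 to 19590740) at 1028, of the UDP-galactose transporter gene Ugalt (FBgn0024994; X, 2703732 to 2704043) at 1020.3 and of the mitochondrial ribosomal protein gene mRpL41 (FBgn0034001; 2R, 15217619 to 15217887) at 918. Among the 20 strongest peaks were promoters of the translation factor gene eIF6 at 729, the arginine methyltransferase gene Art3 at 721, the Polycomb group gene ph-p at 706, the RNA-processing gene PNPase at 657 and the chromodomain gene Chro at 615. Promoter peaks were also assigned to Tcs5 at 759.7, CG5611 at 739, CG7601 at 695, CenG1A at 691, Fkbp14 at 660.2 and CG18549 at 581. Introns held the peaks of the transcription factor gene Adf1 at 657, CG32772 at 627, the high mobility group gene HmgZ at 623 and Trl, which encodes GAGA factor, at 617. The peak assigned to CG4004, at 803, lay at a promoter of a gene that is not protein-coding, 5071 bp from the TSS of CG4004. All 20 peaks overlapped a thresholded peak in both replicates.

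The replicates shared most of their strong sites. Of the 925 thresholded peaks of replicate 1, 627 (67.8%, Wilson 95% interval 64.7 to 70.7%) overlapped a thresholded peak of replicate 2, and 617 of 1098 (56.2%, 53.2 to 59.1%) did so in the other direction. Peaks of replicate 1 placed at random on their own arms overlapped 0.446% on average over 1000 placements, and 1.30% at most. Against the ranked list of replicate 2, 857 peaks (92.6%) overlapped, where 100 random placements gave 42.5%. Of the 1404 conservative peaks, 619 overlapped both replicates' thresholded lists and 342 neither. Across 1389 conservative peaks with a ranked peak in both replicates, signal values had a Spearman correlation of 0.66 and a Pearson correlation of 0.82 on the log2 scale. The IDR selects peaks that rank alike in both peak sets, so a positive correlation among selected peaks follows from the selection and no p is given. The median log2 ratio of replicate 2 to replicate 1 was 0.04, with an SD over peaks of 0.46. Across all 54525 ranked peaks found in both replicates the Spearman correlation was 0.23, and across the 53029 that did not pass it was 0.18. Peaks are not independent replicates.

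**Figure D1:**
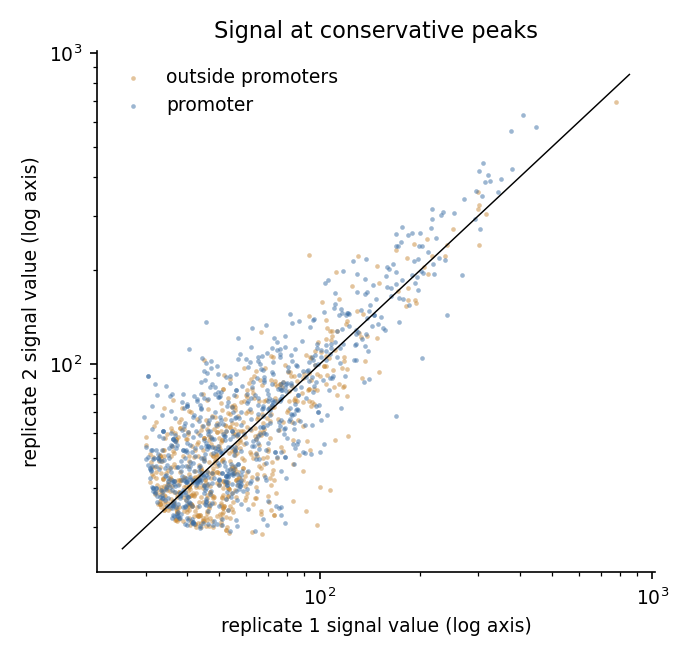
Signal value of each conservative peak in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), in the authors' units, with blue points for promoter-proximal peaks, orange points for the others and a line of equality. The points scatter around the line (Spearman correlation 0.66 over 1389 peaks).

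Promoters held the largest share of conservative summits. Of 1402 summits, 750 (53.5%, Wilson 95% interval 50.9 to 56.1%) lay within 500 bp of a TSS, against 14.1% of 125327 ranked peaks that did not pass (odds ratio 7.03, Fisher's exact adjusted p = 2.05e-258). Introns held 463 summits (33.0% against 38.0%, Fisher's exact adjusted p = 0.000186) and intergenic sequence 159 (11.3% against 24.5%, adjusted p = 1.31e-34). Coding sequence held 9 summits (0.642% against 19.2%, odds ratio 0.0272, Fisher's exact adjusted p = 8.11e-112). The 3′ UTR class held 7 (Fisher's exact adjusted p = 8.76e-08), the 5′ UTR class 5 (adjusted p = 0.0201) and non-coding exons 9 (adjusted p = 0.391). Around protein-coding genes, the 705 summits within 500 bp of the nearest TSS had a median position of -122 bp, and 85.1% were upstream of it.

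**Figure D2:**
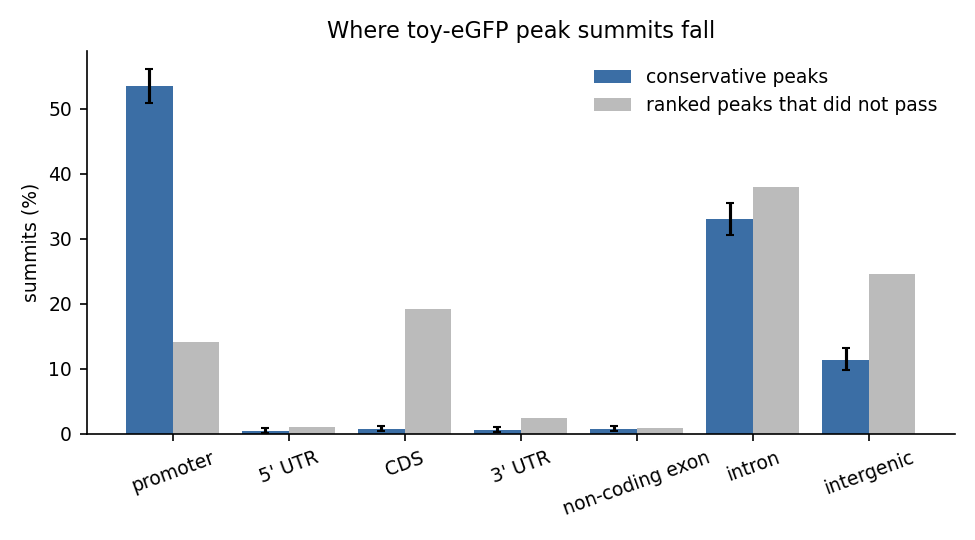
Share of summits (vertical, percent) in each annotation class for 1402 conservative peaks (blue, bars with Wilson 95% intervals) and 125327 ranked peaks that did not pass (grey). Promoters hold 53.5% of conservative summits and 14.1% of the others, and coding sequence 0.642% and 19.2%.

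Promoter peaks were also stronger than other conservative peaks. Their median signal value was 116 (interquartile range 86.4 to 170, 750 peaks), against 98.1 (79.2 to 137, 652 peaks) elsewhere, a difference of 17.8 (2-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The same sign was found in replicate 1 alone (72.1 against 65.2, permutation p = 0.00248) and in replicate 2 alone (70.5 against 59.8, permutation p = 3e-05). In replicate 1 the difference was 6.80.

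Conservative peaks were spread over the long arms, with 301 on 3R, 297 on 3L, 289 on X, 267 on 2L and 246 on 2R. Arm 3R held fewer than its share of ranked peaks (21.5% against 25.2%, odds ratio 0.812, Fisher's exact adjusted p = 0.00895). The odds ratio passed in replicate 2 alone (0.792, Fisher's exact adjusted p = 0.0111) and in the pooled list (0.856, adjusted p = 0.0355). It did not pass in replicate 1 alone (0.835, Fisher's exact adjusted p = 0.181), in peaks above the median signal (0.821, adjusted p = 0.228) or at an IDR of 0.001 (0.815, adjusted p = 0.201). Of 51 ranked peaks at the list's IDR that are outside the list, 28 are on 3R, where they count in the background. Y held 0 of 1402 (Wilson 95% upper limit 0.273%) against 517 of the ranked peaks that did not pass (Fisher's exact adjusted p = 0.0187). The pooled list had 2 peaks on Y (Fisher's exact adjusted p = 0.0525), replicate 2 alone had 2 (adjusted p = 0.689) and replicate 1 alone had 0 (adjusted p = 1), none past adjustment. Chromosome 4, which carries toy, ey and the Pax2-type gene sv, held 2 conservative peaks (0.143%, Wilson 95% interval 0.0391 to 0.519%), against 93 ranked peaks that did not pass (0.0742%, odds ratio 1.92, Fisher's exact adjusted p = 0.330). Against the length of the arms, the odds ratio for chromosome 4 turned to 0.144 (exact binomial p = 0.000202). By length it was 0.0949 in replicate 2 alone (exact binomial p = 0.000814) but 0.993 in replicate 1 alone (exact binomial p = 1), so the low share by length was absent without replicate 2. The replicates differed here: replicate 1 had 9 thresholded and 481 ranked peaks on chromosome 4, replicate 2 had 1 and 94, while replicate 2 had more ranked peaks on each long arm.

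At toy itself (FBgn0019650; 4, 989725 to 1007922, dm6), the conservative list held 0 peaks within 20 kb. Replicate 1 had 4 thresholded peaks in this window. The strongest, with a signal value of 122, was intergenic (4, 982837 to 983152), and another (4, 989546 to 989861; 82.5) lay 21 bp from the TSS of toy. The remaining peaks were intergenic (4, 985491 to 985806; 76.7) and at a promoter beyond the gene (4, 1027138 to 1027453; 114). Replicate 2 had 0 thresholded and 0 ranked peaks in the window, and the pooled list had 1, at the last of these sites (4, 1027200 to 1027380), with a signal value of 312. No peak near toy passed in both replicates. At the last site the pooled signal value, 312, was well above replicate 1's 114. At the peak of CG11050 the series gave 1490.1, and the replicates 775 and 694. The lack of a replicate 2 peak is therefore not evidence that replicate 2 had no signal there.

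**Figure D3:**
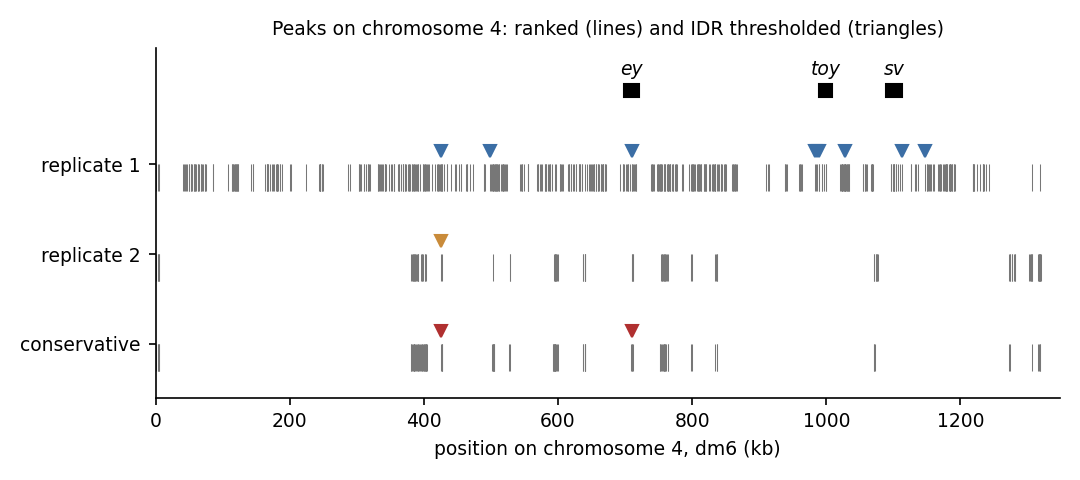
Peaks along chromosome 4 (horizontal, dm6 position in kb) in replicate 1, replicate 2 and the conservative list with its ranked list, with ranked peaks as grey lines, thresholded peaks as triangles and the genes ey, toy and sv as black boxes. Replicate 1 shows 481 ranked and 9 thresholded peaks, and replicate 2 shows 94 and 1 with long empty stretches.

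Retinal determination genes, the network under ey and toy in the eye primordium, were bound no more often than matched genes. Of 15 with a ranked peak, 2 had a conservative peak, against 2.37 in matched random lists (permutation adjusted p = 1). One was ey (FBgn0005558), with an intronic peak (4, 709697 to 710036, dm6) 2438 bp from the TSS, a signal value of 81.7 and rank 1064; replicate 1 gave 50.5 and replicate 2 gave 32.0, and the peak passed the threshold in replicate 1 but not in replicate 2. The other was the TALE homeobox gene hth (FBgn0001235), with an intronic peak (3R, 10597612 to 10597951) 16494 bp from the TSS, a signal value of 136 and thresholded peaks in both replicates. The conservative list had 0 peaks assigned to so, eya, dac, Optix or eyg, which had 12, 44, 25, 35 and 20 ranked peaks, and the pooled list had 1, at so; these unbound genes were chosen after their values were seen. Of 8 Pax family genes with a ranked peak, 1 was bound, again ey (matched mean 0.910, permutation adjusted p = 1), and the others, prd, gsb, gsb-n, Poxm, Poxn, eyg and toe, were not. Among photoreceptor and phototransduction genes 3 of 16 were bound (matched mean 1.77, permutation adjusted p = 1): norpA, the phospholipase C of phototransduction, in an intron at 426, and rdgC and rdgB at promoters at 239 and 77.6. The gene toy had no peak in the ranked list used and was outside the retinal determination and Pax family tests, as was sv for the Pax family. In replicate 1 alone, 3 of 16 retinal determination genes (matched mean 2.13) and 2 of 10 Pax family genes (0.890) were bound. The peaks come from whole embryos, so sites bound in the eye primordium alone may have been missed. This was not tested.

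Ribosomal protein genes were the single list of 19 above its matched lists, which were not matched on gene expression. Conservative peaks were assigned to 31 of 73 of them, against a mean of 5.95 (central 95% of matched lists 2 to 11; permutation adjusted p = 0.000380, unadjusted p = 2e-05, the smallest that 100000 random lists can give). In replicate 1 alone the count was 18 of 89 (matched mean 4.16), in replicate 2 alone 25 of 68 (4.94) and at an IDR of 0.001 10 of 73 (2.80, permutation adjusted p = 0.0171), each past adjustment. The peak of RpS28b was stronger in replicate 2 (137) than in replicate 1 (45.5). The strongest were promoter peaks of RpS27 (3R, 25247430 to 25247616) at 295, RpL41 (2R, 24903840 to 24904179) at 200.3, RpL32 (3R, 30046098 to 30046437) at 188 and RpS28b (X, 9554530 to 9554660) at 169, each within 107 bp of the TSS. The small list of other housekeeping genes had 2 of 7 bound (matched mean 0.629, permutation adjusted p = 0.788): Act5C at 149, with a peak 4677 bp from its TSS, and eEF1alpha1 at 122, at the promoter.

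Lists of muscle, epidermis and trachea, and signalling genes did not pass after adjustment. Muscle genes had 6 of 15 bound (matched mean 1.87, permutation p = 0.0113, adjusted p = 0.108), led by the cardiac and visceral muscle regulator tin at 180.1, then sls at 112, Mef2 at 85.9 and bin at 79.5. Epidermis and tracheal genes had 6 of 14 (matched mean 2.18, permutation p = 0.0221, adjusted p = 0.140), led by shn at 211, vvl at 106, grh at 106 and trh at 102. Notch and EGFR signalling genes had 6 of 19 (matched mean 2.68, permutation adjusted p = 0.368), the strongest being aos at 189.9, spi at 162, aop at 159 and sty at 130.4, while Egfr, vn, rho and kek1, chosen after their values were seen, were not bound. Fisher's exact test without matching took all 13968 protein-coding genes as background in place of the 11541 with a ranked peak. Under it these lists passed too, with Fisher's exact adjusted p of 0.00459, 0.00443 and 0.0141. With matching, in replicate 1 alone 3 of 15 muscle genes (matched mean 1.81) and 5 of 14 epidermis and tracheal genes (1.98) were bound. In replicate 2 alone the counts were 4 of 14 (1.46) and 2 of 13 (1.47).

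Neural and patterning lists did not differ from their matched lists past adjustment. Neuroblast and proneural genes had 0 of 17 bound (matched mean 2.46, permutation p = 0.130, adjusted p = 0.493), and neurosecretory and insulin-like peptide genes 0 of 12 (matched mean 1.28, p = 0.509). The neuroblast temporal series had 4 of 15 (matched mean 2.54): chinmo at 341, slp2 at 153, grh at 106 and hb at 89.6. Mushroom body and brain differentiation genes had 3 of 18 (matched mean 2.87), chinmo, otp at 100.2 and ey. Pan-neuronal genes had 2 of 13 (matched mean 1.78), elav at 332 and cpo at 155, and glial genes 2 of 12 (matched mean 1.5), moody at 324 and pnt at 114. Head gap genes had 3 of 15 (matched mean 2.28; slp2, hb and cnc at 75.9), pair-rule and segment polarity genes 3 of 17 (matched mean 2.95; en at 94.8, ptc at 94.4 and hry at 72.4), dorsoventral genes 3 of 17 (matched mean 2.82; sog at 105, dpp at 96.6 and Doc2 at 95.5), and Hox genes 1 of 8 (matched mean 1.56; abd-A at 72.5). Endoderm, fat body and hemocyte genes had 1 of 14 (matched mean 1.98; ush at 65.7). None of these lists passed, and each adjusted p other than that of the neuroblast and proneural list was 1. Some strongest peaks named here and above lay far from the TSS: 33851 bp for vvl, 20816 for hry, 12470 for chinmo, 12147 for pnt and 7888 for sty. With assignment limited to 5 kb, pair-rule and segment polarity genes had 1 of 17 bound and dorsoventral genes 1 of 17. The neuroblast temporal series kept 4 of 15.

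**Figure D4:**
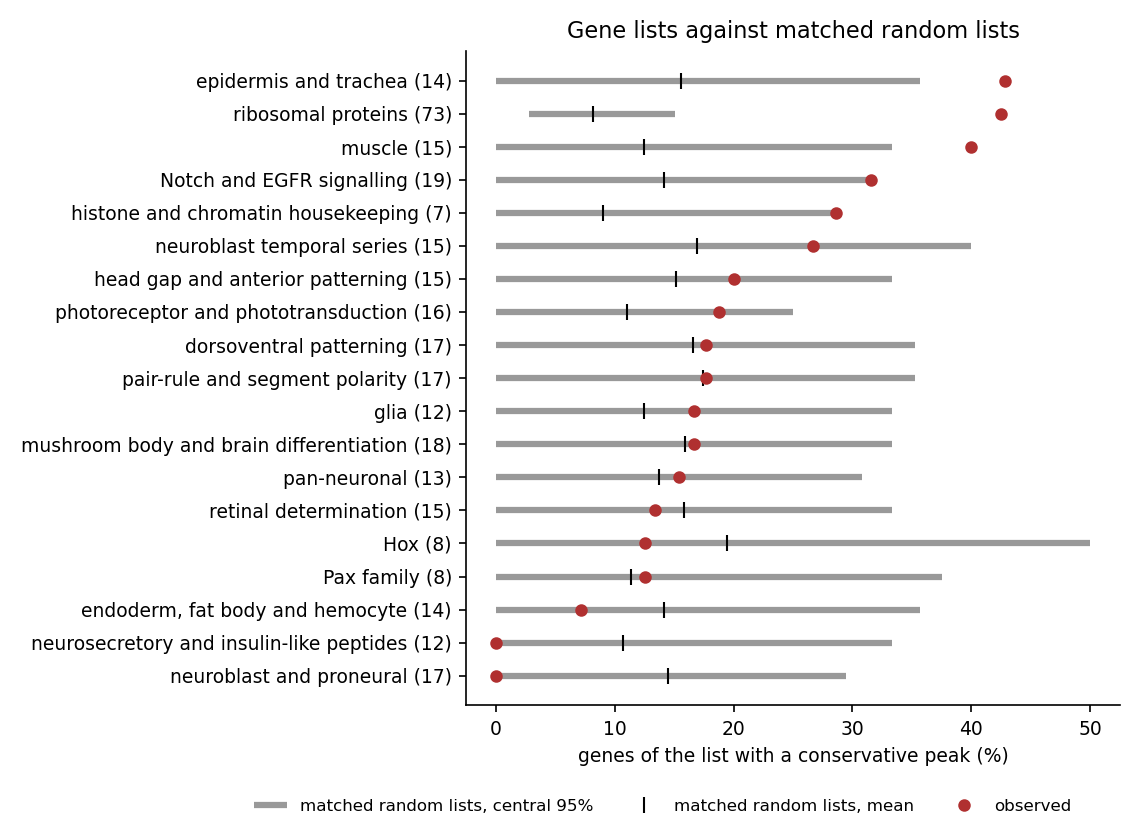
Percent of the genes of each list with a conservative peak (horizontal), as observed (red points), with the mean (black tick) and central 95% (grey bar) of 100000 matched random lists; numbers in brackets are genes with a ranked peak. Ribosomal protein genes, 31 of 73, are the list that passed after adjustment.

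Paired domain sites, the expected target sequence of a Pax6-type protein, were as frequent at summits as in the flanks. The 11 bp consensus TTCACGCWTSA with up to 2 mismatches was found in 10.6% of 1369 summit windows (Wilson 95% interval 9.07 to 12.3%) and 10.4% of flanks (exact McNemar adjusted p = 1), and the shorter core TCACGCWTSA in 2.48% and 2.19% (adjusted p = 0.831). The consensus written backwards, a control for composition, gave 14.1% and 14.2% (exact McNemar adjusted p = 1). The paired-class homeodomain dimer TAATNNNATTA with up to 1 mismatch was found in 32.3% of summits and 19.3% of flanks (exact McNemar adjusted p = 8.56e-14), and the homeodomain core TAATTA in 15.7% and 11.1% (adjusted p = 0.00254, but 0.0864 with flanks on the other side). Windows at summits had 37.1% G and C and flanks 42.6%, and 4 of 5 rearranged sites of the same bases had a larger summit-to-flank difference than the dimer. The DRE, TATCGATA, a core promoter element, was found in 2.19% and 0.584% (exact McNemar adjusted p = 0.00254, and 1.88% against 0.433% at an adjusted p of 0.0691 in the 693 windows of peaks above the median signal). The other fixed motifs did not pass in these windows: GAGA factor sites stood at 4.09% and 3.73%, Motif 1 at 4.82% and 3.43%, CACA repeats at 3.43% and 4.97%, Zelda sites at 0.584% and 1.39%, proneural E-boxes at 8.11% and 8.91%, Twist E-boxes at 8.04% and 9.64%, and initiators at 15.9% and 18.0%. In the widest windows GAGA factor sites passed (15.5% against 7.10%, exact McNemar adjusted p = 3.10e-11), as did Motif 1 (11.6% against 6.21%, adjusted p = 2.06e-06) and proneural E-boxes (22.2% against 18.5%, adjusted p = 0.0305), while initiators were depleted (29.5% against 33.9%, adjusted p = 0.0305). In the narrowest windows CACA repeats were depleted (1.24% against 2.91%, exact McNemar adjusted p = 0.0104), and in peaks above the median signal Twist E-boxes were (6.64% against 10.8%, exact McNemar adjusted p = 0.0282). Proneural E-boxes had the opposite direction against ranked peaks that did not pass (7.92% against 10.8%, Fisher's exact adjusted p = 0.0249). There Twist E-boxes, Zelda sites and initiators were also depleted and Motif 1 was enriched. G and C differed more in this comparison than against flanks (37.2% at summits against 46.9% in the ranked peaks). Base composition was therefore not held equal, and its part in these differences was not tested.

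**Figure D5:**
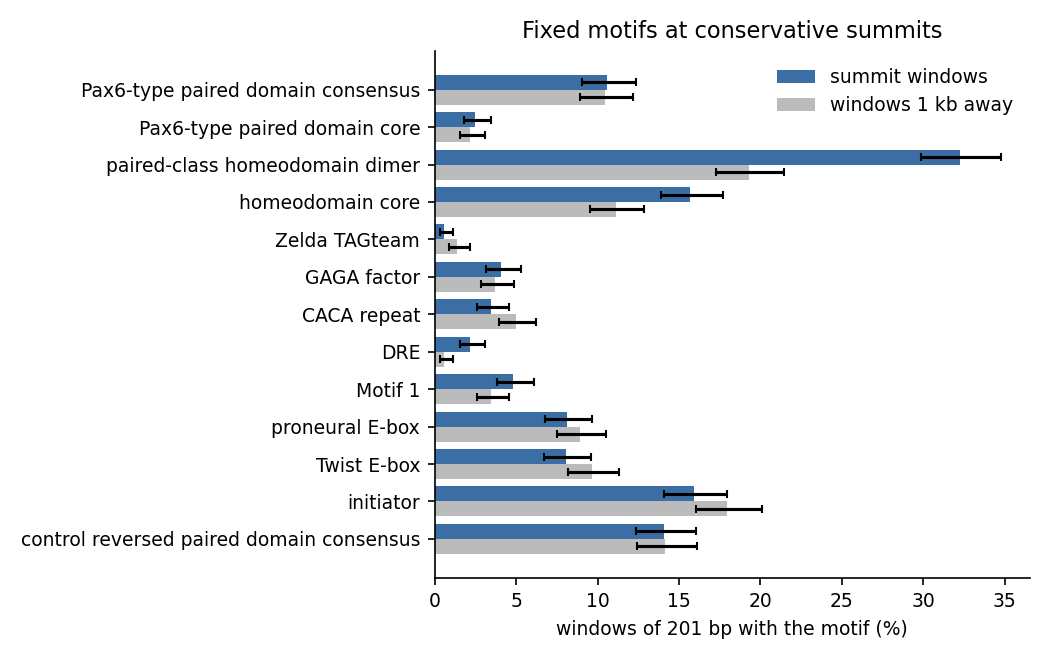
Percent of 1369 windows with each fixed motif (horizontal) at conservative summits (blue) and 1 kb away (grey), with Wilson 95% intervals. The homeodomain dimer (32.3% against 19.3%), the homeodomain core and the DRE are more frequent at summits, and the paired domain consensus (10.6% against 10.4%) is not.

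Among all strand-collapsed 6-mers, 262 were more frequent at summits and 461 less frequent (exact McNemar, adjusted p under 0.05). Of the 10 with the smallest p, 9 were made of A and T alone: ATTTTA (45.7% of summits against 24.8% of flanks, exact McNemar adjusted p = 2.87e-26), AAATAT (49.1% against 28.3%), ATATTA (33.6% against 15.9%), AAAATA, TAAATA, TTAAAA, ATTTAA, TTTAAA and AAAAAT. The exception was ACAGTG, in 20.7% of summits and 8.04% of flanks (exact McNemar adjusted p = 6.51e-19). All 10 were also enriched against ranked peaks that did not pass, matched on promoter class. These peaks were not equal to the summits in G and C (46.9% against 37.2% at summits).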

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

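All values in this part were chosen after they were seen and were not tested. Replicate 2 had 32 thresholded peaks on scaffolds outside the arms and the pooled list 12, where replicate 1 had 0 and the conservative list 2. These peaks were not used in comparisons by arm or gene, and all of them are on scaffolds assigned to X without a position. A further 51 ranked peaks met the conservative list's own IDR of 0.01 and are not in that list, and the 47 of them on arms were used as background only. They include 28 on 3R, 16 on 2L and 3 on 2R. The strongest on an arm (2L, 480944 to 481233, dm6), 1401 bp from a TSS of cbt, had a signal value of 967 and would have ranked 4 in the list, and another near Lk6 (3R, 11760925 to 11761173) had 669.7. Peaks left out also lay nearest to Rh5, the strongest of them at 130, and to RpL13A, at 73.7. Rh5 is in the photoreceptor and phototransduction list and RpL13A in the ribosomal protein list, and both were counted as unbound. On an unplaced scaffold, 1 peak with a signal value of 1170.4 would have ranked 2. Why these peaks are outside the list is not given in the sources used here, and no explanation was tested.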

How the results depend on the processing

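The alternatives named here as added were chosen after seeing the data; the others were planned. Of 67 alternative values, 13 moved, 3 reversed and 51 did not, 5 of these under the planned IDR under 0.01, which removes no peak and says nothing about stability. An odds ratio was called reversed when it crossed 1, whatever its p. All 3 were the odds ratio for chromosome 4 against arm length, and the value in replicate 1 alone, 0.993, shows no difference. The promoter odds ratio (5.52 to 9.54) and the promoter signal difference (6.80 to 19.6) passed under every alternative run. The peak count was 925 to 1098 in single replicates and 581 at an added IDR of 0.001. The shared part of replicate 1 was 59.1% at a reciprocal overlap of 50%, 64.2% for summits within 100 bp and 92.6% against the ranked list. The signal correlation was 0.82 as Pearson's r of log2 values, and 0.23 over all ranked peaks and 0.18 over those that did not pass (both added). The odds ratio for chromosome 4 was 1.13 in replicate 2 alone and 1.65 in replicate 1 alone, and reversed to 0.144 against arm length. With both choices changed together (added), it was 0.0949 in replicate 2 alone but 0.993 in replicate 1 alone (exact binomial p = 1), so the low share by length rests on replicate 2. The number of gene lists rose from 1 to 4 under Fisher's exact test. That test dropped the matching on ranked peaks and also took all 13968 protein-coding genes as background, so the rise cannot be put down to either choice. Peaks near toy numbered 1 in the pooled list and 0 to 4 in single replicates. Enriched motifs rose from 3 to 6 in the widest windows, which added GAGA factor (15.5% against 7.10%), Motif 1 (11.6% against 6.21%) and the proneural E-box (22.2% against 18.5%). They fell to 2 with flanks toward lower coordinates, where the homeodomain core no longer passed (15.5% against 12.3%, exact McNemar adjusted p = 0.0864), and to 2 in peaks above the median signal or at IDR 0.001, where the DRE no longer passed (adjusted p = 0.0691 and 0.113) with fewer windows, at 1.88% against 0.433% and 1.74% against 0.348%. Twist E-boxes were depleted in peaks above the median signal (6.64% against 10.8%) and CACA repeats in the narrowest windows (1.24% against 2.91%). Against ranked peaks in place of flanks, 4 motifs were enriched, with Motif 1 added (Fisher's exact adjusted p = 0.0249), and enriched 6-mers rose from 262 to 424. There the proneural E-box turned to depleted (7.92% against 10.8%). Also depleted were the Twist E-box (8.13% against 11.6%), Zelda sites (0.571% against 1.5%) and the initiator (Fisher's exact adjusted p = 0.0380). Depleted 6-mers rose from 461 to 766. Summits had 37.2% G and C and these ranked peaks 46.9%, so base composition was not held equal in this comparison. Except where the construction shows it, the cause was not tested. No paired analysis was possible because there is 1 group. Depth is unknown, and with 2 replicates a missing peak is not evidence of absent binding.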

Other observations

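The tests of gene families, ribosomal promoters, the DRE and every aspect of chromosome 4, and those of ACAGTG on separate arms, against other promoter peaks and by distance, were chosen only after the result, or one close to it, was seen. Among 8 gene families defined by symbol, cytochrome P450 genes had 0 of 72 members with a conservative peak (matched mean 6.86, permutation p = 0.00136, adjusted p = 0.00544 over 100000 matched lists). Odorant and gustatory receptor genes had 1 of 105, Gr89a (matched mean 9.81, permutation adjusted p = 0.00544). Mitochondrial ribosomal protein genes had 2 of 49 (matched mean 3.64), translation initiation factor genes 3 of 31 (2.91), proteasome genes 1 of 38 (3.19), complex I genes 1 of 26 (2.65) and cuticle protein genes 1 of 59 (5.01), none past adjustment. Ecdysone-induced genes had 3 of 6 (1.27, permutation adjusted p = 0.447), and Eip75B alone had 5 peaks.

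Cytoplasmic ribosomal protein genes stood apart even among genes with a ranked peak at their own promoter: 31 of 64 had a conservative promoter peak, against 634 of 8853 other genes (48.4% against 7.16%, odds ratio 12.2, Fisher's exact p = 9.72e-19). Gene expression was not held equal in this comparison. Signal that the tag or antibody gives at these promoters without toy was not tested. The gene with the most conservative peaks, chosen after its value was seen, was CG43245 with 6, and CHES-1-like, Hr4, Pdp1, Rtnl1, sbb, shn and tara had 5 each. The DRE, TATCGATA, had the largest excess at summits among 12 mirrored 8-mers made of the same bases (30 windows against 8; the next, ATTCGAAT, 18 against 8).

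On chromosome 4, replicate 2 had 0.195 times as many ranked peaks as replicate 1, while the ratio on the 5 long arms was 1.34 to 1.48. Even thinning of the peaks along the chromosome is argued against: replicate 2 had no ranked peak over 376 kb (4, 5033 to 380695, dm6), where replicate 1 had 118, and 10000 random draws of 94 replicate 1 peaks left at most 239 kb. A general loss of heterochromatin would lower the ratio next to the centromeres, yet in the 1 Mb of each long arm nearest its centromere it was 5.41, against 1.38 in the rest of the arms, and on Y it was 18.3. Extra copies of toy DNA in the tagged line would be shared by both replicates, so alone they would not give a difference between them. For replicate 1's own peaks near toy they stay open. Its 21 ranked peaks there had a median signal value 5.05 above the rest of chromosome 4 (20.3 against 15.2, permutation p = 0.0197). Replicate 2 had 0 ranked peaks there, so the same comparison could not be made in it. The pooled ranked list, made from the alignments of both replicates, held 9 peaks in the 376 kb stretch and 158 on chromosome 4. Replicate 1 alone held 118 and 481. At the promoter beyond toy (4, 1027200 to 1027380), the pooled signal value was 312 and replicate 1's was 114, although replicate 2 had no ranked peak there. At that site a missing peak is therefore not evidence of missing signal in replicate 2. Elsewhere on chromosome 4, peak lists cannot show whether reads or only listed peaks were missing in replicate 2, and the calling of the lists was not tested. Differences between the embryo collections or libraries may also account for the pattern and were not tested. No biological explanation was tested, since both replicates are of 1 group.

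The homeodomain dimer at summits is consistent with AT-rich sequence alone. Of the 5 other mirrored sites built by rearranging TAAT around the same spacer, 4 had a larger difference between summit and flank than TAATNNNATTA. Its difference less that of ATATNNNATAT (16.2 percentage points) was -3.21 points (bootstrap 95% interval -7.52 to 0.95). Binding through the homeodomain of toy is not excluded by this test. No biological explanation was tested.

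ACAGTG is harder to place. Picked on 2L, 2R, 4, X and Y as the 6-mer with 3 G or C and the smallest p, it had on 3L and 3R a summit-to-flank ratio of 2.87 (19.1% against 6.64%), above all other 6-mers with 3 G or C and above the highest ratio, 1.82, of 1000 shuffles of each window's own bases, which argues against base composition as the whole cause. Promoter sequence in general is argued against too, since 18.1% of conservative promoter summits had it and 9.43% of promoter peaks that did not pass (Fisher's exact p = 1.02e-12), and it was not tied to promoters, with 23.5% of other summits against 9.22% of their flanks (exact McNemar p = 9.05e-12). A candidate explanation, found on the same data and not tested, is a sequence-specific factor at these sites; signal that the tag or antibody gives without toy was not tested either, nor was any biological explanation. Against direct contact at the summit stands that 34.5% of its 304 sites lay within 50 bp of it, against a median of 52.6% for the 640 6-mers with 3 G or C (central 95% 39.2 to 66.7%, 2 lower).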
